A study of Mus musculus with 26 samples.

How the data were processed

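RNA was measured in 26 libraries of cells sorted from mouse sarcomas, grouped by their labels into 11 libraries of the metastatic clone (MC), 9 of clones that did not metastasise (Non-MC) and 6 of lung metastases (Lung-Met). Per the labels' protocols, tumours were digested and the cells were sorted at once by fluorescent reporters expressed from Rosa26, RNA was extracted with a Norgen kit for single cells, and Illumina libraries were made. Trim Galore, STAR, HTSeq and DESeq2 are named in the submitters' processing notes, without versions. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are reported.

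The authors deposited a table of raw read counts per Ensembl gene for each library, with 38561 genes, and these counts were the input of every test. HTSeq's rows of reads without a gene were kept out of library sizes and tests. Reads in no feature made up 8 to 17.9% of the reads counted per library, and ambiguous reads 0.532 to 0.719%. The authors also deposited 1 table of normalised signal for the whole series, with 20353 genes in 19 columns. Each of its columns was a count table divided by 1 factor, and whole reads were recovered for 100% of its values at a tolerance of 0.01. These reads equalled the deposited counts gene by gene, with 12 columns holding 1 library and 7 holding the sum of 2: MC 1 and 2, MC 3 and 4, MC 5 and 6, MC 7 and 8, MC 10 and 11, Non-MC 1 and 2, and Lung-Met 4 and 5. Symbols came from a GENCODE M21 name table, which held 36639 of the 38561 identifiers, and otherwise from the authors' table. Reads shared between near-identical copies, such as Hspa1a with Hspa1b, Hba-a1 or the Hbb, Gzm and Prl2c families, can be divided or lost by the counting, so single members of these families are uncertain.

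Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the 3 groups and a minimum count of 10, which left 16980 genes. The main test was edgeR's quasi-likelihood test with robust estimation, TMM factors and group as the only term, fitted on all 26 libraries, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a gene comes from this test unless another is named. Levels are CPM from edgeR, counts scaled to a common library size with TMM factors, and log2 CPM used a prior count of 2. Gene lists were tested with camera with the correlation between genes estimated from the data, adjusted over 34 lists with at least 3 tested members. A preset correlation of 0.01 was an alternative. The count of members that passed is given over all genes and adjusted over the list alone.

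The lists, the test, the samples in each fit and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among genes past the threshold with at least 1 CPM on average over both groups, leaving out unnamed gene models, pseudogenes and receptor or immunoglobulin segments. The study's candidates Rasd1, Reck and Aldh1a2 were added in every comparison, and in each list the 4 members with the smallest p that passed, or otherwise 2 members as values. Genes named outside this rule are marked in the text as chosen after their values were seen. The lists were study candidates, metastasis suppressors, mesenchymal transition factors, collagens and matrix, matrix proteases and inhibitors, cell cycle, hypoxia and glycolysis, interferon response, antigen presentation class I, inflammatory cytokines, immediate early and heat shock, TGF-beta targets, p53 targets, ERK pathway output, unfolded protein and amino acid stress, cholesterol synthesis, retinoic acid pathway, imprinted genes, Hox genes, oxidative phosphorylation, ribosomal proteins, mitochondrial genome and sex-linked genes, the last untested. Lists of cell types that a sort could hold were skeletal muscle, lung epithelium, macrophage and monocyte, neutrophil, T and NK cell, B cell, endothelial, erythroid, pericyte and smooth muscle, fibroblast, adipocyte and Schwann cell.

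The alternatives were RLE factors, scaling by library size alone, DESeq2 1.42.0, limma voom with sample quality weights, quasi-likelihood without robust estimation, no low-count filter, a filter of 1 CPM in 6 libraries, fits on the 2 groups compared, the replicate number as a block, and leaving out each library in turn. After the data were seen, 6 more were added: the libraries summed as in the authors' table, with edgeR or DESeq2, the closest libraries summed, no libraries with at least 50 CPM of Ptprc, that choice together with the summing, and the mean log2 CPM of the endothelial and macrophage lists as 2 covariates. Replicate numbers were checked through the correlation of same-numbered libraries' deviations from their group means.

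The test was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For MC against Non-MC it recovered 50% and 80% of them over 16793 genes, with 0.763% false calls. For Lung-Met against MC it recovered 39% and 82% over 16795 genes with 3.2% false calls, and for Lung-Met against Non-MC 45% and 77% over 16802 genes with 6.15%. A list raised in the simulation was called in each of the 3 comparisons and other lists were called 0 times. The simulated libraries and genes were drawn independently, and the simulated lists held random genes. Libraries that lie close together and genes that vary together were thus not represented, so these rates do not measure the error in the data. Libraries held 33200434 to 50229081 reads in genes, at which 3 counts, taken as the limit of a count of 0, equal 0.0597 to 0.0904 CPM. These limits cover counting error only, since reads without molecular identifiers are not independent molecules.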

Results

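Gene expression was compared between sorted cells of the metastatic clone in primary sarcomas (MC, 11 libraries), of primary clones that did not metastasise (Non-MC, 9) and of lung metastases (Lung-Met, 6). Reads counted in genes ranged from 33200434 to 50229081 per library. The labels do not say that libraries come from separate animals, so each p measures spread between libraries. The authors' table adds 7 pairs of libraries together, which leaves 6 MC, 8 Non-MC and 5 Lung-Met columns. The summed MC pairs lay 0.38 to 0.56 apart (root mean square log2 distance) and other MC pairs 0.96 to 1.73, so p on 26 libraries can be too small. Non-MC 3 and 4 (0.44), Lung-Met 3 and 4 (0.53) and Non-MC 6 and 7 (0.67) stay separate among the 19 columns, so p there can be too small as well. Results on these 19 columns, a setting chosen after the data were seen, stand beside those on 26 libraries.

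Fibroblast markers and pericyte and smooth muscle markers were lower as lists in the metastatic clone than in the clones that did not metastasise. Of single genes, Col14a1, a collagen that binds to fibrils, was at 32.9 CPM in MC (SD 11.6, n 11) and 264 in Non-MC (SD 109, n 9). Its log2 fold change was -3.01 (SE 0.31, adjusted p = 6.15e-06). Svep1, a matrix adhesion protein, was at 16.1 CPM (SD 8.58) and 160 (SD 94.3), log2 -3.32 (SE 0.36, adjusted p = 6.15e-06). Every MC library lay below every Non-MC library for both genes. Igfbp7, a secreted binding protein of insulin-like growth factors, fell by 2.4 on the log2 scale (SE 0.27), and Entpd2, an ectonucleotidase, by 2.89 (SE 0.31). On the 19 columns the adjusted p was 0.00432 for Col14a1, 0.00427 for Svep1, 0.00197 for Igfbp7 and 0.00432 for Entpd2. These 4 genes were chosen after their values were seen.

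Fibroblast markers fell as a list, with 4 of 11 members lower, 0 higher and 7 not passed (6 lower adjusted over the list alone). Its median was log2 -0.88 (list adjusted p = 0.000644, on 19 columns 0.000809). The 4 were Col15a1 (log2 -2.21, SE 0.38), Pi16 (-2.63), Clec3b (-2.7) and Gsn (-1.66). With edgeR 1 of them passed on the 19 columns, Col15a1 (6 of 11 members lower at an unadjusted p under 0.05, 3 of 11 with DESeq2), and without those rich in Ptprc 0 passed (5 of 11 unadjusted). Pericyte and smooth muscle markers fell too, with 6 of 10 lower, 0 higher and 4 not passed (7 lower adjusted over the list alone). The median was -2.06 (list adjusted p = 0.00106, on 19 columns 0.00342), and it did not pass with endothelial and macrophage covariates (0.167) or on the 19 columns without those rich in Ptprc (0.0553). Among them were Rgs5, a regulator of G protein signalling (-3.42, SE 0.48), Kcnj8 (-3.62) and Abcc9 (-3.92, SE 0.64), which form a potassium channel, and the adhesion molecule Mcam (-2.42). Of the 6, edgeR passed Rgs5, Abcc9 and Mcam on the 19 columns (6 of 10 members unadjusted, 5 of 10 with DESeq2), and without those rich in Ptprc 0 passed (6 of 10 unadjusted). Of the endothelial markers 10 of 12 fell (12 adjusted over the list alone). They included Esam (-2.88), Emcn (-3.97), the receptor Tie1 (-3.21) and the transcription factor Erg (-2.53). Esam and Emcn also passed with edgeR on the 19 columns (11 unadjusted, 10 with DESeq2), and without those rich in Ptprc 0 (12 unadjusted). The list as a whole had a median of -2.54 and did not pass (adjusted p = 0.114). Its level varied within Non-MC: Pecam1 was at 415 CPM in Non-MC 5 and at 75.4 on average (SD 130). Emcn reached 172 CPM in its highest Non-MC library against 31.7 on average (SD 54.1). Of the collagens and matrix genes 8 of 29 fell and 0 rose (19 lower adjusted over the list alone; median -1). Those that fell included Eln, the elastin of elastic fibres (-2.32), Sparc (-1.07), Mfap5 (-1.61) and Col12a1 (-2.34). The list's adjusted p was 0.0596 on 26 libraries and 0.0357 on 19 columns, where edgeR passed 0 of 29 members (19 lower unadjusted) and DESeq2 10. Without libraries rich in Ptprc it was 0.267 and with covariates 0.309, with 1 of 29 lower in each.

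The study's candidates Aldh1a2, Reck and Rasd1 all fell (3 of 3, also adjusted over the list alone; list adjusted p = 0.000856, on 19 columns 0.00353). The study chose them, which makes this not independent evidence of their direction. Aldh1a2, an enzyme that makes retinoic acid, was at 5.79 CPM in MC (SD 3.97) and 56.4 in Non-MC (SD 54.5), log2 -3.28 (SE 0.63, adjusted p = 0.00285). Reck, an inhibitor of matrix metalloproteases, was at 8.06 (SD 6.35) and 23.8 (SD 5.46), log2 -1.56 (SE 0.35, adjusted p = 0.0115). Rasd1, a small GTPase induced by glucocorticoids, was at 9.13 (SD 3.24) and 23.2 (SD 16.4), log2 -1.34 (SE 0.32, adjusted p = 0.0163). With edgeR on the 19 columns, fitted as unpaired, none of the 3 passed as a single gene (adjusted p = 0.0829 for Aldh1a2, 0.111 for Reck and 0.237 for Rasd1). In the 6 pairs of units given under other observations, Reck and Rasd1 were lower in MC in 6 of 6 and Aldh1a2 in 5 of 6. The smallest fall was only log2 -0.16 for Reck and -0.17 for Rasd1. Of 16972 genes 7.39% were lower in 6 of 6. That pairing was read from the same libraries, and no paired fit was made. With DESeq2 on these columns Aldh1a2 (0.00037) and Reck (0.00596) passed and Rasd1 (0.0844) did not. Without Non-MC 2 the call of Rasd1, MC vs Non-MC, was lost (-1.08, adjusted p = 0.0527). With endothelial and macrophage covariates 2 of 3 candidates passed (list adjusted p = 0.0149). On the 19 columns without those rich in Ptprc 0 of 3 passed (0.0434), and on the libraries without those rich in Ptprc 3 of 3 (0.0158).

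**Figure D1:**
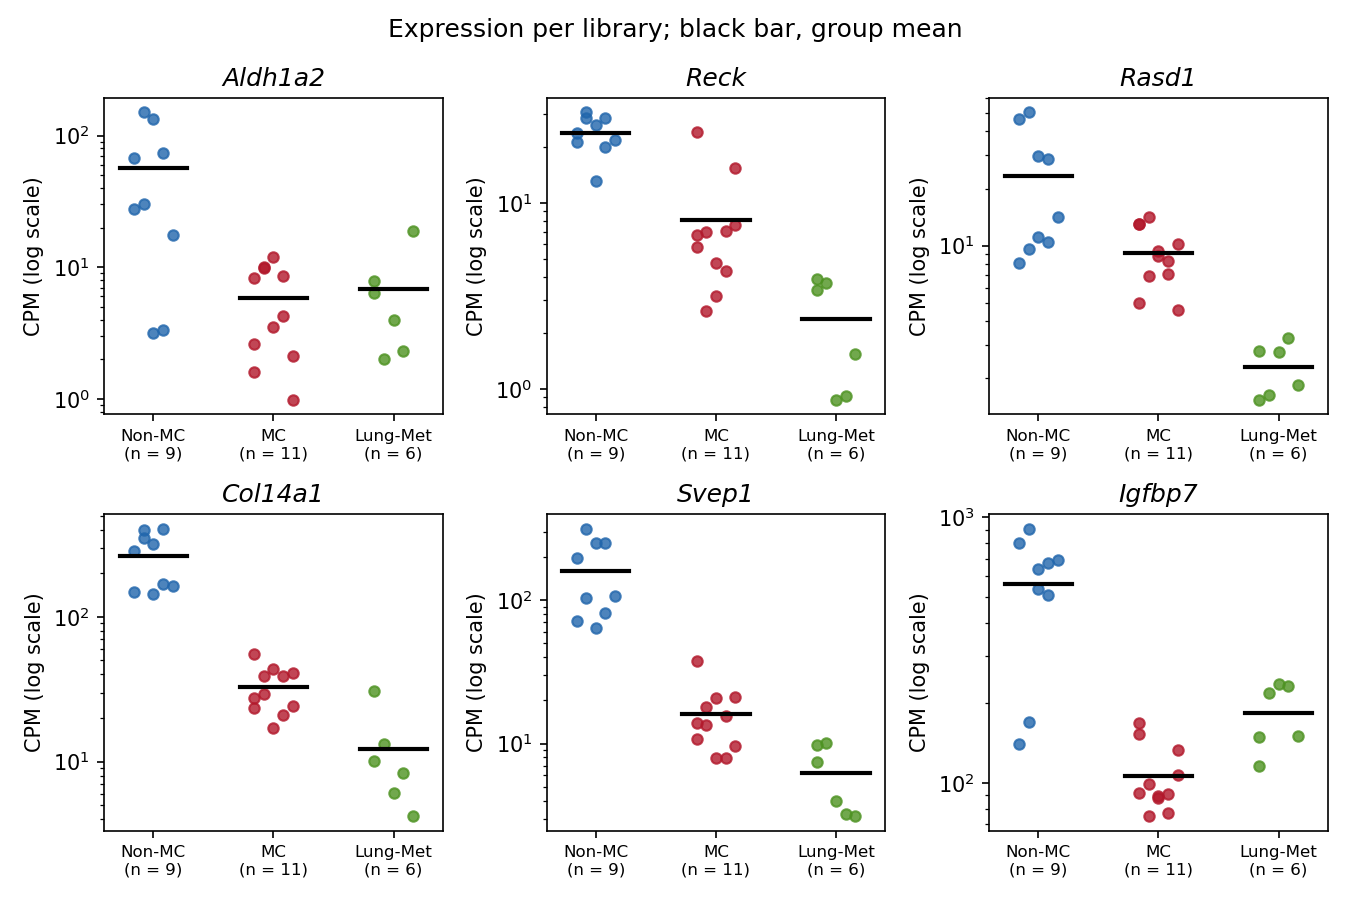
CPM on a log axis of Aldh1a2, Reck, Rasd1, Col14a1, Svep1 and Igfbp7 in Non-MC, MC and Lung-Met, with dots for libraries and bars for group means. Col14a1 lay between 17.1 and 55.3 CPM in MC libraries and between 143 and 406 in Non-MC libraries, while Aldh1a2 spread more widely in Non-MC (mean 56.4, SD 54.5).

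The largest falls among named genes were in Fga, a chain of fibrinogen (log2 -4.54, SE 1), the granule protein Chga (-4.48), the retinol-esterifying enzyme Lrat (-4.34), the adhesion molecule Nfasc (-4.17, SE 0.73; 1.4 CPM in MC and 25.2 in Non-MC). Others were Ly6k (-4.1), Shisal1 (-4.08), Higd1b (-3.97, SE 0.6), the granzymes Gzmc (-3.96) and Gzmd (-3.92), and the leptin receptor Lepr (-3.86, SE 0.6). Several were near the detection floor in MC, such as Chga at 0.167 CPM. Without Non-MC 5 the call of Chga, MC vs Non-MC, was lost (-2.12, adjusted p = 0.22), and with endothelial and macrophage covariates its direction reversed. Single Non-MC libraries held much of some means. The highest was at 25 CPM for Fga (mean 4.9), 57.2 for Gzmc (12.8), 21 for Shisal1 (4.54) and 12.7 for Lrat (2.8). Genes that rose were fewer and changed less. They were the transcription factors Foxq1 (2.06) and Lef1 (1.51, SE 0.41), the junction protein Ctnnd2 (1.86), Rab11fip1 of recycling endosomes (1.8, SE 0.41; 70.4 CPM against 20.2) and Wwc1 (1.63). The rest were the adhesion molecule Cadm1 (1.61), Sult2b1 (1.53), the noncoding RNA Wincr1 (1.4, SE 0.32), Depdc7 (1.27), the transporter Slc4a11 (1.12, SE 0.24), the nuclease Dna2 (1.07) and Zfp184 (1.05). Of all genes higher in MC, 3 passed on the 19 columns as well: Wincr1 (adjusted p = 0.0406), and, chosen after their values were seen, the urea cycle enzyme Asl (log2 0.64; 0.0401) and the deubiquitinase Uchl5 (0.76; 0.0324).

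Single members passed in lists that did not. Of the cell cycle genes 4 of 30 rose and 0 fell (15 higher adjusted over the list alone; median 0.45, list adjusted p = 0.225): Mcm5 (0.61), Ccnb1 (0.75), Mcm3 (0.73) and Mcm7 (0.65). Of the Hox genes 3 of 18 fell, Hoxb5 (-3.46), Hoxb6 (-3.19) and Hoxb7 (-2.41), with a list median of -0.28 (adjusted p = 0.629; 3 lower adjusted over the list alone). In the TGF-beta targets Tgfbi rose (1.01, SE 0.22; list median -0.16, adjusted p = 0.728; 1 higher adjusted over the list alone). In the inflammatory cytokines Cxcl5 fell (-2.74; list median -0.15, adjusted p = 0.779; 1 higher and 2 lower adjusted over the list alone). Adamts5 fell among the matrix proteases and inhibitors (-2.16; list median -0.36, adjusted p = 0.654; 3 lower adjusted over the list alone), and Zim1 among the imprinted genes (list median -0.26, adjusted p = 0.654; 1 lower adjusted over the list alone). So did Dlc1 among the metastasis suppressors (-1.06; list median 0.01, mean -0.1, adjusted p = 0.792; 2 lower adjusted over the list alone). In the retinoic acid pathway 1 of 14 fell, which was Aldh1a2 (list median -0.21, adjusted p = 0.153; 1 higher and 2 lower adjusted over the list alone). Hoxb5 and Hoxb6 also passed with edgeR on the 19 columns, but 0 cell cycle genes did (15 higher unadjusted, 4 with DESeq2), nor did the other single members in this paragraph.

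No member passed in the other lists of cell types. The macrophage and monocyte list had a median of 1.37 (adjusted p = 0.779), and its level differed between libraries of the same group. Without libraries rich in Ptprc the median turned to -1.43 (1 of 16 lower, list adjusted p = 0.267), and to -0.52 on the 19 columns without those. The leukocyte gene Ptprc was at 572 CPM in MC 7, 506 in MC 8, 121 in MC 9, 76.3 in MC 5, 120 in Non-MC 6, 59 in Non-MC 8 and 249 in Lung-Met 2, and below 50 in the remaining libraries. T and NK cell markers had a median of -2.54 (7 lower adjusted over the list alone, adjusted p = 0.654), B cell -1.28 (0.779), neutrophil 0.45 (0.928, with camera's direction down; median -1.26 without libraries rich in Ptprc), erythroid -0.86 (0.654), adipocyte -1.62 (0.654; 3 lower adjusted over the list alone) and Schwann cell -0.79 (0.728; 2 lower adjusted over the list alone). Skeletal muscle was at -0.26 (0.811) and lung epithelium at 0.69 (0.928; -0.05 with DESeq2, -0.89 without libraries rich in Ptprc). On the 19 columns the skeletal muscle median was 0.69.

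**Figure D2:**
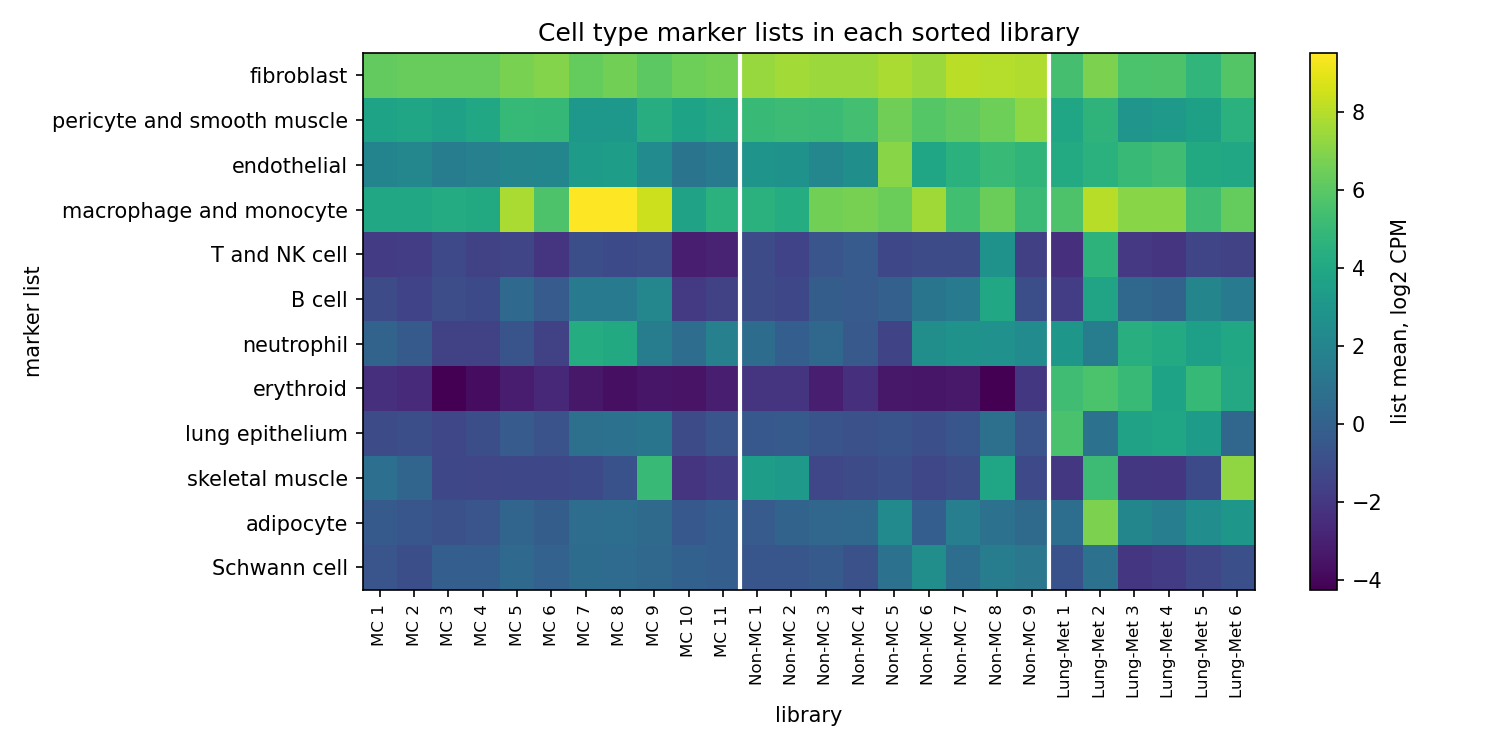
Heat map of the mean log2 CPM of 12 lists of cell type markers (vertical) in each of the 26 libraries (horizontal, by group), with colour for the list mean. The macrophage and monocyte list reached 9.5 in MC 7 and MC 8 against 3.69 in MC 10, and the endothelial list was at 7.05 in Non-MC 5.

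No member passed in the remaining lists either. Medians and list adjusted p were -0.1 and 0.611 for mesenchymal transition factors (0.02 with library-size scaling; 1 lower adjusted over the list alone), 0.22 and 0.611 for oxidative phosphorylation, -0.33 and 0.654 for the mitochondrial genome, 0.21 and 0.654 for ribosomal proteins, -0.16 and 0.707 for immediate early and heat shock genes, and 0.2 and 0.707 for cholesterol synthesis. They were 0.14 and 0.728 for unfolded protein and amino acid stress, 0.19 and 0.751 for hypoxia and glycolysis, -0.01 (mean 0.13, and 0.13 as median with library-size scaling) and 0.779 for p53 targets, 0.18 and 0.833 for interferon response, 0.02 and 0.928 for antigen presentation class I, and 0.03 and 0.955 for ERK pathway output. The sex-linked genes were not tested, and Xist was at 190 CPM in MC (SD 202), 212 in Non-MC (SD 212) and 147 in Lung-Met (SD 229).

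With edgeR, 560 of 16980 genes changed between MC and Non-MC, 110 higher and 450 lower, and 296 rose and 391 fell with scaling by library size alone. Of the genes that fell 395 were at least 2-fold lower. On the 19 columns 70 changed, 3 higher and 67 lower, all of them among the 560, and 522 with DESeq2. The count of 560 was 364 without Non-MC 7, with 291 lower. The count of 110 higher genes was 54 without MC 1, 63 without MC 2, 56 without MC 3, 63 without MC 4, 187 without MC 9, 58 without Non-MC 3, 58 without Non-MC 4 and 73 without Non-MC 7. Of the 27 named genes, 4 passed with edgeR on the 19 columns (Higd1b, Emcn, Abcc9 and Wincr1), 22 passed there with DESeq2, and 15 lost their call when 1 library was left out. On the columns without those rich in Ptprc (4 MC and 6 Non-MC) edgeR called 0 genes, with 1857 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0846. On the libraries without those rich in Ptprc it called 670.

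Immediate early and heat shock genes were far lower in lung metastases than in the metastatic clone of primary tumours. Hspa1a, an inducible chaperone, was at 576 CPM in MC (SD 433, n 11) and 3.5 in Lung-Met (SD 1.39, n 6), a log2 fold change of -7.36 (SE 0.67, adjusted p = 4.12e-08). The transcription factor Atf3 fell by 5.08 on the log2 scale (SE 0.35, adjusted p = 2.64e-10), and Fosb went from 999 CPM to 25.2 (-5.31, SE 0.64; 13.1 CPM without Lung-Met 6). Of the list 18 of 20 fell and 0 rose (19 lower adjusted over the list alone; median -3.2, list adjusted p = 2.63e-07, on 19 columns 4.81e-06). Zfp36, which destabilises cytokine messages (-4.24), and Btg2 (-2.99) were also among the 4 smallest p. The list mean was between 4.71 and 6.18 log2 CPM in Lung-Met libraries and 8.88 or higher in every primary library. Site and the handling of tissue before the sort cannot be told apart in any comparison with Lung-Met, because each group comes from 1 site.

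Inflammatory cytokines fell as a list, with 16 of 21 lower and 0 higher (16 adjusted over the list alone; median -2.74, list adjusted p = 0.0132, on 19 columns 0.0109). They included the inhibitors of NF-kappaB signalling Nfkbia (-3.09, SE 0.2) and Tnfaip3 (-4.38), the chemokine Cxcl1 (-4.84) and the macrophage growth factor Csf1 (-3.38). Genes of unfolded protein and amino acid stress fell, with 10 of 15 lower and 0 higher (12 adjusted over the list alone; median -0.89, list adjusted p = 0.00445, on 19 columns 0.0109). Among them were the transcription factors Ddit3 (-1.81), Atf5 (-2.19) and Atf4 (-0.9) and the chaperone Dnajb9 (-1.12). TGF-beta targets fell, with 10 of 14 lower and 0 higher (10 adjusted over the list alone; median -1.58, list adjusted p = 0.015, on 19 columns 0.0135). Among them were Tgfbi (-1.95), Pmepa1 (-1.68), Smad7, an inhibitor of the pathway (-1.76), and Ccn1 (-2.61). The 9 tested genes of the mitochondrial genome all rose (9 adjusted over the list alone; median 1.42, list adjusted p = 0.0365, on 19 columns 0.0154). This list did not pass with the closest libraries summed (0.0871, 7 of 9 higher), with covariates (0.0755, 7 of 9), without libraries rich in Ptprc (0.103, 7 of 9) or on the 19 columns without those (0.0551). The call of list mitochondrial genome, Lung-Met vs MC, was also lost without MC 3 (0.058), MC 11 (0.0506), Lung-Met 2 (0.0515) or Lung-Met 6 (0.0524). Examples were mt-Nd1 from 601 CPM to 2510 (2.06, SE 0.21), mt-Rnr2 (2.36), mt-Cytb (1.59) and mt-Nd4 (1.49).

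**Figure D3:**
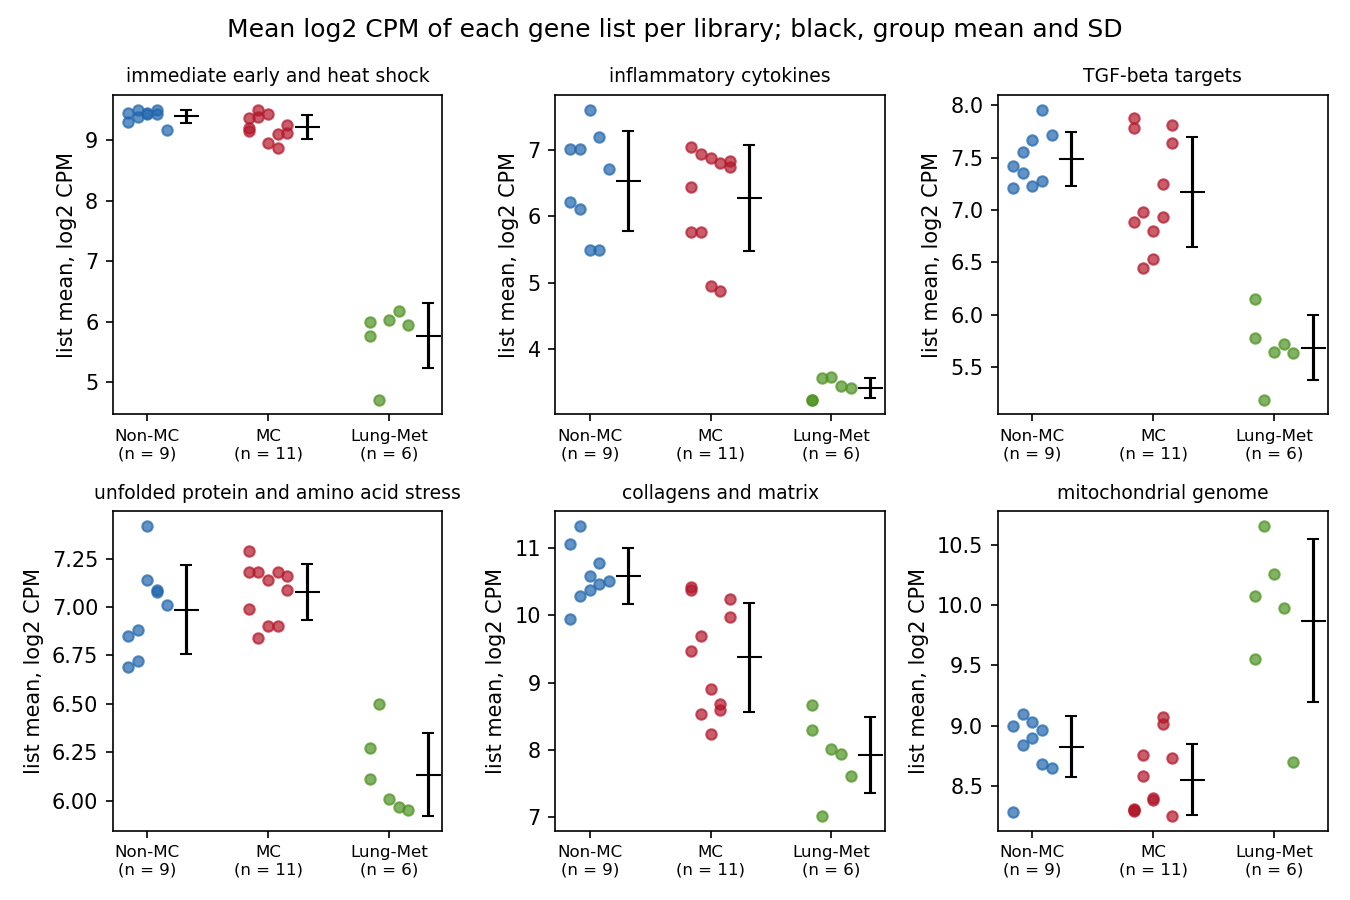
Mean log2 CPM per library of 6 gene lists (immediate early and heat shock, inflammatory cytokines, TGF-beta targets, unfolded protein and amino acid stress, collagens and matrix, mitochondrial genome) in Non-MC, MC and Lung-Met, with dots for libraries and the group mean with SD. Lung-Met libraries lay between 4.71 and 6.18 for immediate early and heat shock genes, against 8.88 to 9.5 in MC.

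The erythroid list rose in Lung-Met, and single genes of lung, muscle and fat rose while their lists did not pass. The erythroid list had 4 of 4 tested members higher (4 adjusted over the list alone; list adjusted p = 9.67e-05, on 19 columns 0.000597). The globin gene Hbb-bs was at 142 CPM (SD 51.2) against 0.285 in MC, Hba-a1 at 36.2, the haem enzyme Alas2 at 13.8 and Hbb-bt at 12.2. Globin reads were in all 6 Lung-Met libraries (Hbb-bs from 78.2 to 215 CPM), while other markers differed between libraries. The surfactant gene Sftpc was at 488 CPM in Lung-Met 1, 86 in Lung-Met 4, 69.8 in Lung-Met 3, 15.6 in Lung-Met 5, 0.131 in Lung-Met 6 and 0 in Lung-Met 2. The skeletal muscle actin Acta1 was at 891 in Lung-Met 2 and 955 in Lung-Met 6, where primary libraries held up to 174 in MC and 77.7 in Non-MC, and the adipocyte hormone Adipoq at 69.4 in Lung-Met 2. The means of the other named genes that rose depended on 1 library. The muscle genes Myh4 (286 CPM, SD 684), Ckm (214, SD 462) and Mybpc2 (58.7, SD 126) were at 7.21, 26.3 and 7.87 without Lung-Met 2. The adipocyte protease Cfd (27.1, SD 58.8) and Thrsp of fat synthesis (7.51, SD 17.6) were at 3.14 and 0.329 without it. The prolactin relative Prl2c3 (174, SD 317) was at 46 without Lung-Met 5, and the airway gene Scgb3a1 (3.23) at 2.02 without Lung-Met 4. As lists, lung epithelium (3 of 6 higher, 4 adjusted over the list alone, adjusted p = 0.116) and adipocyte genes (4 of 5, 5 adjusted over the list alone, 0.231) did not pass. With DESeq2 10 of 14 lung epithelium genes were higher. Without libraries rich in Ptprc 4 of 5 were higher with edgeR (list adjusted p = 0.0568). In that setting 7 of 9 neutrophil (0.102) and 12 of 16 macrophage and monocyte genes (0.182) were higher too. With all libraries 3 of 9 and 0 of 16 were. Skeletal muscle (7 of 15, 4 on 19 columns, 9 adjusted over the list alone; 0.764), T and NK cell (9 of 11, 5 on 19 columns, 9 adjusted over the list alone; 0.7) and endothelial genes (9 of 12, 10 adjusted over the list alone; 0.189) did not pass. The T and NK cell list mean was 4.66 log2 CPM in Lung-Met 2 and at most -1.38 in the other Lung-Met libraries, and without libraries rich in Ptprc 1 of 9 members was higher with a median of -0.41 (4.13 with all). Endothelial members that rose included Vwf (3.88) and Cldn5 (3.3).

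The other named genes that fell were the chaperone Hspa1b (-6.39, SE 0.62), the growth factor Gdf15 (-6.52, SE 0.94; 56.6 CPM to 0.61) and the cytokine Tnf (-6.23). So did the immediate early genes Arc (-6.18, SE 0.56; 248 CPM to 3.4, or 2.05 without Lung-Met 5) and Egr4 (-6.12), Rpl39l (-6.67), Jakmip2 (-5.74), Ctnna2 (-5.44), Trim69 (-5.23) and the interleukin antagonist Il1rn (-5.14). Jakmip2 (0.0288 CPM), Ctnna2 (0.0563), Egr4 (0.0681) and Rpl39l (0.0689) were near or below the detection floor in Lung-Met, so their fold changes depend on it. Of the candidates, Reck (-1.75, SE 0.43, adjusted p = 0.00394, on 19 columns 0.0292) and Rasd1 (-1.99, SE 0.4, adjusted p = 0.00071, on 19 columns 0.00817) fell. Aldh1a2 was at 0.25 (SE 0.67, adjusted p = 0.813; 6.89 CPM, SD 6.24, and 4.52 without Lung-Met 5). Its direction reversed without Lung-Met 5, with voom and with covariates. As a list the candidates did not pass (2 of 3 lower, also adjusted over the list alone; adjusted p = 0.179). With endothelial and macrophage covariates 0 of 3 passed as single genes (list median -1.35). Of the collagens and matrix genes 16 of 29 fell (17 adjusted over the list alone; list adjusted p = 0.227), with Col1a1 going from 6990 CPM to 722 (-3.27, SE 0.46). Of the imprinted genes 6 of 18 fell (7 adjusted over the list alone; list adjusted p = 0.189), among them the neighbouring noncoding RNAs Meg3 (-3.98, SE 0.65), Rian (-4.05) and Mirg (-4.62). In hypoxia and glycolysis 10 of 23 rose and 2 fell (10 and 3 adjusted over the list alone; list adjusted p = 0.367), with Bnip3 (1.9) and Pdk1 (1.67) higher. In oxidative phosphorylation 20 of 29 rose (9 on 19 columns, 22 adjusted over the list alone; 0.231). ERK pathway output (6 of 18 lower, 7 adjusted over the list alone; 0.116; Phlda1 -3.08) and p53 targets (3 higher and 6 lower of 17, also adjusted over the list alone; 0.116) did not pass as lists. With endothelial and macrophage covariates the p53 list passed (0 higher and 3 lower of 17, median -0.37, list adjusted p = 0.0435).

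With edgeR, 4788 genes changed between Lung-Met and MC, 2708 higher and 2080 lower, and 3675 rose and 1383 fell with scaling by library size alone. At least 2-fold changes were 1257 higher and 1136 lower. On the 19 columns 2723 changed, of which 2705 were among the 4788. Of the named genes Rpl39l did not pass on the 19 columns (adjusted p = 0.0601). On the 19 columns without those rich in Ptprc the TGF-beta targets did not pass (0.0551). Without libraries rich in Ptprc the inflammatory cytokines (0.0568), TGF-beta targets (0.0621) and mitochondrial genome (0.103) did not pass, while their medians stayed at -2.73, -1.61 and 1.26. There 23 of 23 interferon response genes (median -2.22, list adjusted p = 0.0621) and 10 of 12 of antigen presentation class I (-2.29, 0.102) were lower. With all libraries 3 of 23 (-0.63, 0.367) and 6 of 12 (-1.25, 0.231) were lower. The interferon list mean was 7.58 log2 CPM in Lung-Met 2, which this setting leaves out, and at most 4.23 in the other Lung-Met libraries. With voom the muscle genes Ckm, Lung-Met vs MC (-0.39), and Mybpc2, Lung-Met vs MC (-0.67), were lower. Reads in no feature were 15% in Lung-Met (SD 2.08) and 10.4% in MC (SD 1.48).

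Fibroblast markers and immediate early genes were lower as lists in lung metastases than in the clones that did not metastasise, and most single collagen genes fell too. Col1a1, a chain of the main fibrillar collagen, was at 16300 CPM in Non-MC (SD 4800, n 9) and 722 in Lung-Met (SD 304, n 6), a log2 fold change of -4.49 (SE 0.49). Cxcl14, a chemokine, went from 975 CPM (SD 869) to 11.6 (-6.39, SE 0.82, adjusted p = 4.05e-06). The candidates fell, with Reck at -3.32 (SE 0.48, adjusted p = 1.48e-05, on 19 columns 0.000197), Rasd1 at -3.33 (SE 0.43, adjusted p = 4.99e-06, on 19 columns 0.000159) and Aldh1a2 at -3.03 (SE 0.8, adjusted p = 0.00491, on 19 columns 0.0109). The study chose this list (3 of 3 lower, also adjusted over the list alone; list adjusted p = 0.0121, on 19 columns 0.0146), so it is not independent evidence.

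Fibroblast markers fell, with 8 of 11 lower, 0 higher and 3 not passed (8 lower and 1 higher adjusted over the list alone; median -1.74, list adjusted p = 0.0137, on 19 columns 0.0146). They included Col15a1 (-4.9), Pi16 (-3.24), the receptor Pdgfrb (-2.09) and Thy1 (-2.08). Of the collagens and matrix genes 25 of 29 fell and 0 rose (27 adjusted over the list alone; median -2.38), among them Col1a2 (-3.7), Col6a3 (-3.67) and Col6a2 (-2.96). The list adjusted p was 0.0554 on 26 libraries, 0.0764 without libraries rich in Ptprc, 0.0893 with covariates and 0.0395 on 19 columns. Pericyte and smooth muscle genes fell in 6 of 10 (9 adjusted over the list alone; list adjusted p = 0.105). The endothelial list had 1 of 12 higher and a median of -0.31 (adjusted p = 0.881). Immediate early and heat shock genes fell in 18 of 20 (18 adjusted over the list alone; median -3.11, list adjusted p = 1.06e-06, on 19 columns 2.64e-05), with Hspa1a at -7.51 (SE 0.68), Hspa1b at -6.46 and Arc at -6.36. Inflammatory cytokines fell as a list (16 of 21 lower, 16 adjusted over the list alone; median -2.88, list adjusted p = 0.0154). So did TGF-beta targets (11 of 14, 12 adjusted over the list alone; -1.61, 0.0154) and unfolded protein and amino acid stress (8 of 15, 8 adjusted over the list alone; -0.75, 0.0167). On 19 columns the 3 lists had adjusted p of 0.0146, 0.0146 and 0.0395. The stress list did not pass with endothelial and macrophage covariates (0.0522). With the replicate number as a block neither the stress list nor the fibroblast list passed, though same numbers are not read as a pairing.

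Other named genes that fell were the cartilage matrix gene Chad (-8.13), the choline transporter Slc5a7 (-7.77), Grin3a (-7.51), Hoxd11 (-7.27), the granzyme Gzme (-6.53), the tendon gene Tnmd (-6.44), Vstm2b (-6.31) and the matrix proteoglycan Kera (-6.13). The highest Non-MC library was at 47.5 CPM for Chad (mean 10.2) and at 224 for Slc5a7 (mean 47.2). Grin3a (0.00816 CPM), Hoxd11 (0.0191), Vstm2b (0.0306), Chad (0.0335) and Kera (0.0644) were near or below the detection floor in Lung-Met, with Grin3a and Hoxd11 at 0 in 4 of 6 libraries, so their fold changes depend on that floor. Erythroid genes rose (4 of 4, also adjusted over the list alone; list adjusted p = 0.00234, on 19 columns 0.0081), with Hbb-bs, Hba-a1, Hbb-bt and Alas2 at the Lung-Met levels already given and at most 0.401 CPM on average in Non-MC. The named genes Myh4, Ckm, Mybpc2, Sftpc and Prl2c3 rose here too, with Slc34a2, a transporter of lung epithelium (17.7 CPM, SD 32.8; 4.41 without Lung-Met 1), the muscle gene Tcap (45.4, SD 82.6; 13.4 without Lung-Met 2) and the mesothelial gene Upk3b (4.65, SD 3.64). Lung epithelium did not pass as a list (4 of 6 higher, 2 of 5 on 19 columns, 6 adjusted over the list alone, adjusted p = 0.123). Only 6 of its 14 genes were tested with edgeR. With DESeq2 13 of 14 were higher. Without libraries rich in Ptprc 5 of 5 were higher with edgeR (list adjusted p = 0.0596). Cell cycle genes rose in 14 of 30 (14 adjusted over the list alone), such as Ccnb1 (1.37) and Cdk1 (1.13), with a list adjusted p of 0.378. Oxidative phosphorylation (24 of 29 higher, 25 adjusted over the list alone; 0.123) and the mitochondrial genome (8 of 9, 8 adjusted over the list alone; 0.123) did not pass as lists. Nor did ribosomal proteins (17 of 30, 21 adjusted over the list alone; 0.245) and hypoxia and glycolysis (14 higher and 3 lower of 23, 15 and 3 adjusted over the list alone; 0.326). Of the imprinted genes 7 of 18 fell (7 adjusted over the list alone; list adjusted p = 0.123), with Meg3 at -4.95 and Rian at -4.91.

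With edgeR, 5856 genes changed between Lung-Met and Non-MC, 3299 higher and 2557 lower, and 5309 rose and 1632 fell with scaling by library size alone. At least 2-fold changes were 1461 higher and 1634 lower. On the 19 columns 5175 changed, 4986 of them among the 5856. Without libraries rich in Ptprc the TGF-beta targets (median -1.43, adjusted p = 0.0539; 0.058 on the 19 columns without those rich in Ptprc) did not pass. There 23 of 23 interferon response genes (-2.04, list adjusted p = 0.0643) and 10 of 12 of antigen presentation class I (-2.33, 0.0764) were lower. With all libraries 1 of 23 (-0.35, 0.462) and 6 of 12 (-1.28, 0.321) were lower. With voom Ckm, Lung-Met vs Non-MC (-1.86), and Mybpc2, Lung-Met vs Non-MC (-0.5), were lower. Of the 450 genes lower in MC than in Non-MC, 259 were also lower in Lung-Met than in Non-MC (57.6%), against 67.77 for independent lists. Of the 110 higher genes 80 were also higher (72.7%), against 21.37. Both comparisons use the same Non-MC libraries, and with these split between them the medians over 20 splits were 114 of 262.5 lower genes (28.73 for independent lists) and 8.5 of 14 higher genes (1.649). In 50 simulations without change too few genes passed to compare shared counts (0 and 0.02 on average). Lists of the observed sizes were therefore taken by rank of p, a test chosen after the result was seen. They shared 202 to 238 lower genes (mean 218) and 75 to 95 higher genes (mean 85.4). The observed 80 higher genes lie within that range, so this test cannot tell their count from an effect of shared Non-MC libraries. The observed 259 lower genes lie above the 202 to 238 of the simulations. Where simulated libraries are drawn independently, the close Non-MC libraries are not represented, so this excess cannot be read as a shared change. With the Non-MC libraries split, higher genes were still shared beyond independent lists, though over a median of only 14 genes. Close Non-MC libraries, such as 1 and 2 or 3 and 4, can fall on both sides of a split. The comparisons then stay tied through them, so the split cannot decide the question.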

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

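All tests reported in this part were chosen only after the result was seen, except the adjustment of the called genes for the endothelial list and the comparison of counts between Lung-Met 3 and 4. Over 200 groups of values, 15 held a library far from the others, where chance flags about 1 in 20 groups, or 10. The number given with each is its gap to the nearest library divided by the range of the group.

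In Non-MC, library 8 stood apart with low Reck (0.497; 3.72 log2 CPM against 4.33 in the nearest library) and with high list means of p53 targets (0.597), lung epithelium (0.662) and T and NK cell markers (0.696). Hbb-bt was high in Non-MC 2 (0.611). In Lung-Met, library 2 stood apart with high Chga (0.735), Lrat (0.779) and Thrsp (0.76), high antigen presentation class I (0.697; list mean 8.11 against 5.6), high T and NK cell markers (0.866; 4.66 against -1.38) and low immediate early and heat shock genes (0.713; 4.71 against 5.76). Wincr1 was high in Lung-Met 5 (0.757), Egr4 was high in Lung-Met 1 (0.803), Higd1b was low in Lung-Met 6 (0.836), and the share of reads in the top 10 genes was high in Lung-Met 3 (0.629; 10% against 6.81%). Reads in no gene, which no comparison used, made up 15% of the reads in Lung-Met on average.

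For the genes called lower in MC than in Non-MC, RNA of endothelial cells in the Non-MC sorts was considered. Over 440 called genes outside the endothelial list, the mean difference was -1.84 (SE 0.21) before and -1.31 (SE 0.2) after adjustment for the endothelial list mean. These genes were selected for their fall in the same libraries, so a difference that remains decides little. For lists fixed beforehand the adjusted difference was -1.08 (SE 0.15) for fibroblast, -1.5 (SE 0.37) for pericyte and smooth muscle and -1.28 (SE 0.4) for collagens and matrix. With the endothelial and macrophage means as covariates, the list test passed for fibroblast (0.0237). It did not pass for pericyte and smooth muscle (0.167, 0 of 10 lower) or for collagens and matrix (0.309, 1 of 29 lower). The values argue against endothelial RNA as the whole cause for the fibroblast list, as far as the endothelial mean measures it and libraries are independent. For pericyte and smooth muscle and for collagens and matrix the question stays open. For dilution by leukocytes in the MC sorts, the mesenchymal list had a median of -0.1 and a mean of -0.19 (SE of the mean over members 0.09). Over the group this argues against a large, even dilution of the genes in that list. In MC 7, 8 and 9, rich in Ptprc, the list mean was 7.25, 7.36 and 7.19 log2 CPM. It was 7.84 in MC 5, also rich in Ptprc, and 7.47 to 7.99 in the remaining MC libraries. A smaller dilution in single libraries stays open. The called genes had -2.27, but they were selected for their fall, so their gap to the list cannot decide the question. Host fibroblasts and pericytes in the Non-MC sorts cannot be told apart from a change within the sarcoma cells, because these cells express many of the same genes (fibroblast list median -0.88), and the sort on a reporter would remove host cells only as far as it is pure. A difference between the clones, which the design names, stays open. Of 100 splits of the libraries 3, the real one included, called as many genes as the real 560 (highest other 885), and of 100 splits of the 19 columns 3 called as many as the real 70 (highest other 196). As many genes were thus rare, but not absent, among splits that move libraries as if independent. Such splits also separate close libraries, so chance between tumours is not excluded. What the splits that called more had in common was not tested.

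Immediate early and heat shock genes were lower in Lung-Met than in MC. An even dilution by lung or muscle cells is argued against as the whole cause, since the mesenchymal list had a median of -0.43 and the immediate early list -3.2. The SE of the mean over members was 0.25 and 0.4, which is a spread between genes and not between libraries. Scaling of the libraries is argued against as well, since the list median was -3.02 with library-size scaling and -3.2 with RLE factors. The lowest primary library lay 2.71 above the highest Lung-Met library, but a difference in handling of the tissues before the sort and a difference between sites cannot be told apart, because each group comes from 1 site. The same holds for inflammatory cytokines (list mean 3.24 to 3.59 log2 CPM in Lung-Met, 4.88 or higher in primary libraries). It also holds for unfolded protein and amino acid stress (at most 6.5 in Lung-Met, 6.69 or higher in primary libraries). Of 100 splits 1, the real one, called as many genes as the real 4788 in Lung-Met against MC (highest other 1117; on 19 columns 1, real 2723, highest other 1600), and 1 called as many as the real 5856 in Lung-Met against Non-MC (highest other 590; on 19 columns 1, real 5175, highest other 1077). This excludes chance at 1 in 100 only for splits that move libraries as if independent, and chance between tumours was not tested. Lung-Met 3 and 4 counted as separate in all of these splits.

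Lung-Met 3 and 4 lay close together (root mean square log2 distance 0.53), while Lung-Met 4 and 5, which the authors' table adds together, lay 1.43 apart, against 0.38 to 0.56 for the other 6 summed pairs. A library sequenced under 2 numbers is argued against by a chi-square per degree of freedom of 62.1 between the counts of Lung-Met 3 and 4. The distances are consistent with Lung-Met 3 and 4 coming from 1 tumour and with a different library being meant in the sum. Separate nodules or clones of 1 animal stay open, and no biological explanation was tested.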

How the results depend on the processing

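The tests on summed libraries, without libraries rich in Ptprc and with covariates were chosen only after the result was seen; the other settings were planned. The count of genes changed in MC against Non-MC (560; 110 higher, 450 lower) moved most. It was 993 (413 higher) with only these 2 groups, 881 (249 higher) with voom, 1112 (334 higher, 778 lower) with DESeq2 and 356 (48 higher) with the replicate block. It was 70 (3 higher, 67 lower) on the libraries summed as in the authors' table, 103 (2 higher, 101 lower) with the closest libraries summed and 234 (73 higher, 161 lower) with endothelial and macrophage covariates. Without leukocyte-rich libraries 169 were higher, and on summed columns without these edgeR called 0 (0 higher, 0 lower; 1857 at an unadjusted p under 0.05), a setting not run with DESeq2. Fewer samples enter the summed settings. The summed MC pairs lay 0.38 to 0.56 apart (root mean square log2 distance), against 0.96 to 1.73 for the other MC pairs. The fit on 26 libraries counts such close libraries as independent, so its p can be too small. The cause was not tested for the other settings. Scaling by library size alone gave 296 higher. It moved the median of all genes from 0.05 to 0.163 in MC against Non-MC, from 0.023 to 0.184 in Lung-Met against MC and from 0.082 to 0.356 in Lung-Met against Non-MC.

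Genes changed in Lung-Met against MC (4788) were 7306 with voom (3570 lower), 2723 on summed libraries (1466 higher, 1257 lower), 1920 with the closest summed (1035 higher, 885 lower), 2202 with covariates (1106 higher, 1096 lower) and 2493 on summed columns without leukocyte-rich ones (1215 higher, 1278 lower), and 1383 were lower with library-size scaling. In Lung-Met against Non-MC 5309 were higher and 1632 lower with library-size scaling, 4157 lower with voom and 1698 lower with the closest summed. A preset correlation called 14, 22 and 23 lists where the estimated correlation called 3, 6 and 7, and without leukocyte-rich libraries 3 passed in Lung-Met against MC. There the cytokines were at 0.0568, the TGF-beta targets at 0.0621 and the mitochondrial genome at 0.103. The mitochondrial genome was also lost with the closest summed (0.0871), covariates (0.0755) and the replicate block (0.0572). The replicate block called 4 lists in MC against Non-MC, with collagens and matrix (0.0478) added to the 3, and 5 in Lung-Met against MC. It called 5 in Lung-Met against Non-MC, where fibroblast markers and unfolded protein and amino acid stress (both 0.0641) did not pass. Same-numbered MC and Non-MC libraries correlated between -0.26 and 0.47 over 9 pairs, with 7 over 0.1 and 3 best with their own number. MC 6 (-0.22) and MC 9 (-0.26) were closer to Non-MC 5 (0.42) and Non-MC 8 (0.66), so the numbers are not read as a pairing.

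Leaving out each library in turn gave 364 to 672 genes in MC against Non-MC (54 to 187 higher, 291 to 536 lower), 3772 to 4994 in Lung-Met against MC (2190 to 2842 higher, 1582 to 2283 lower) and 5036 to 5992 in Lung-Met against Non-MC (2894 to 3454 higher, 2142 to 2701 lower), with 3 to 4, 5 to 7 and 7 to 9 lists. The lowest total came without Non-MC 7, and the higher count was 54 without MC 1 and 187 without MC 9. In MC against Non-MC 15 of the 27 named genes lost their call in at least 1 refit (Cadm1, Chga, Ctnnd2, Depdc7, Dna2, Foxq1, Gzmc, Gzmd, Lef1, Lrat, Ly6k, Rasd1, Shisal1, Wwc1 and Zfp184). Chga was at -2.12 (adjusted p = 0.22) without Non-MC 5, and Rasd1 at -1.08 (0.0527) without Non-MC 2. Named genes that kept their call there were 27 with RLE factors, 26 with DESeq2, 12 with voom, 10 with the replicate block and 8 with covariates. Directions reversed for Aldh1a2 in Lung-Met against MC, which was not called (-0.08 with voom, -1.88 with covariates, -0.36 without Lung-Met 5), for Chga (0.44 with covariates), and with voom for Ckm, Lung-Met vs MC (-0.39), Ckm, Lung-Met vs Non-MC (-1.86), and Mybpc2 (-0.67 and -0.5). The cause was not tested.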

Other observations

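The test of shared tumours was chosen only after the result was seen. Kras and Cd74 were chosen after their values were seen and are given as values only.

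The oncogene Kras was at 143 CPM in MC (SD 103), 107 in Non-MC (SD 47.2) and 250 in Lung-Met (SD 287), and the Lung-Met mean was 135 without Lung-Met 5 (826). The class II invariant chain Cd74 of antigen-presenting cells was at 2910 (SD 4060) in MC, 1080 (SD 839) in Non-MC and 354 (SD 455; 170 without Lung-Met 2) in Lung-Met.

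A hypothesis is that the MC and Non-MC libraries come from the same 6 tumours, so that their deviations from the group means are shared. Units were paired by sex-linked genes, Kras, Trp53, Acta1 and the order of the numbers, and these genes were left out of the test. Genes that vary with them stayed in, so the test is not separate from the choice of pairs. For example, the skeletal muscle list mean was 5.03 log2 CPM in MC 9 and 3.89 in Non-MC 8, which were paired. The correlations, across genes, which are not independent replicates, had a mean of 0.54 over the 6 pairs, and 1 of 720 pairings, the real one, gave as high a mean (highest other 0.41). The permutation p of 0.00139 is the smallest these pairings can give. In 6 of 6 pairs the partner was the best match, which is consistent with shared tumours, although the pairing was read from the same libraries. Within these pairs Reck and Rasd1 were lower in MC in 6 of 6 and Aldh1a2 in 5 of 6, where 7.39% of 16972 genes were lower in 6 of 6. The smallest fall was log2 -0.16 for Reck and -0.17 for Rasd1. No fit with this pairing was made, and the p of MC against Non-MC treat the libraries as independent.

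The overlap of the MC and Lung-Met changes against Non-MC came with a correlation of fold changes across genes of 0.356, against 0.461 in simulations without change, where the shared Non-MC libraries alone give it. The covariance was 0.329 against 0.105, a difference of 0.224. Where simulated libraries are drawn independently, the close Non-MC libraries are not represented. The difference can then be too large and cannot be read as a shared change. With the Non-MC libraries split between the comparisons the correlation was 0.108 and the covariance 0.117. Close Non-MC libraries can fall on both sides of such a split, so these values need not come from a shared change.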
